A study of Mus musculus with 6 samples.

How the data were processed

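Total RNA came from 1 pool of tissue per training group, as far as the labels tell, and was labelled with biotin as cRNA (15 ug per the labels' protocols) for arrays of 1 colour. The labels end in A, B or C, and the values came as 3 tables with different probe sets and 2 columns each, 1 per training group. The letters were therefore read as array designs and not as replicates. The labels do not say whether the arrays of a group carried the same RNA.

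The deposited values were read as log2 signals, 1 per probe set and array. The log base is inferred from their range, 1.40 to 12.53 over the probe sets of all arrays without controls, and the summarization, background correction and normalization that the authors used are not given in the sources used here. The arrays of a design had nearly equal medians before any step taken here, and their signals correlated across probe sets with a Pearson r of 0.995 on design A, 0.991 on B and 0.994 on C.

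Of the 36701 probe sets left after 198 control probe sets were set aside, 29137 had a single gene symbol in the platform annotation, 718 had several and 6846 none. Symbols were brought up to date through the gene identifier with the RefSeq gene table of assembly GRCm38.p6, which matched 29044 of the probe sets with a single symbol. Probe sets with several symbols were not used for genes. Which transcript a probe set reads was taken from the platform annotation and not checked against sequence, and all gene and list values rest on it. No coordinates are given, since no genome build is tied to the values.

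Within each design the paired array was shifted so that the median log2 ratio, paired over unpaired, of probe sets at or above the median signal was 0. The shifts were 0.010, 0.008 and 0.007 for designs A, B and C. Signals under the 25th percentile of a design were set to it, and probe sets whose mean signal lay at or above the design's median were kept: 6211, 6206 and 5934, or 18351 in all. No kept probe set had an array at the floor. Designs were never normalized together. A gene's value was the mean log2 ratio over its kept probe sets with a single symbol, over all designs, for 10581 genes, of which 3437 had 2 or more.

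With 1 array per group and design no test across samples was possible, so probe sets were counted by size, at 2-fold and 1.5-fold. Named genes were chosen by rule. The first part took genes with 2 or more kept probe sets, all in one direction and each at least 1.5-fold apart, up to 10 per direction. The second took the 4 kept probe sets with the largest log2 ratio per direction and design, and the third the 2 to 4 genes of each list with the largest absolute log2 ratio. Pcp2, Cldn11, Syt2, Nfkbia, Xist, Uty, Eif2s3y, Kdm5d and, in the closing part, Nefm and the genes of the second lists were named after their values were seen. Fos, Arc and Npas4 were named because they were not measured above the signal filter.

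There were 29 gene lists, 15 of processes and 14 of cell type markers, of which 28 had the 5 measured genes needed. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on 10 bins of signal rank and on the number of probe sets (1, 2, or 3 and more). A list outside the central 95% is said to stand apart. The percentile describes these pools and is not a p-value. The groups, lists, filters, thresholds, naming rule and most alternatives were fixed before the data were examined.

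Repeatability was described by Pearson correlation, across genes, with Fisher's 95% interval. It used the log2 ratios of the first pair of kept probe sets of a gene in alphabetical order. A second measure was the share of probe sets that went the same way as the mean of their gene's other kept probe sets. Its exact binomial interval does not allow for genes that enter with several probe sets. Both measure probe and array error, not the spread between pools of mice.

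Alternatives were no scaling, quantile scaling, loess scaling (span 0.3), no floor, a floor at the median, no signal filter, signal at or above the 75th percentile, each design alone, the brightest probe set per gene, and counting probe sets with several symbols for each symbol. The brightest probe set was the one with the highest signal rank within its design. Leaving out probe sets with a letter suffix, leaving out Gabra6, the control probe sets under the other scalings, and second lists of granule cell, Purkinje cell and oligodendrocyte markers were added after seeing the data.

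The steps were tested on simulated data made from the real signals. Of probe sets changed 2-fold, 98.0% were found past 1.5-fold, against 51.3% of those changed 1.5-fold and 0.34% of unchanged ones, among 18351 probe sets. Lists of 20 genes shifted by 0.2 stood apart in 97.5% of simulations, those shifted by 0.1 in 48.5%, and unshifted ones in 5%, among 10594 genes. The simulated noise of a log2 ratio had an SD of 0.2. Simulated lists were drawn at random from all genes, so the 5% was set by construction. These rates may not hold for lists whose genes vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.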

Results

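Gene expression was measured in the deep cerebellar nuclei of male C57BL/6 mice, in tissue centred on the anterior interpositus nucleus, a cerebellar output nucleus needed for the conditioned eyeblink. The mice were 11 to 18 weeks old per the labels. They had been trained for 7 days with a tone of 352 ms and a shock of 100 ms next to the eye. In the paired group the shock started 252 ms after the tone and ended with it. In the unpaired group tone and shock came separately, in a pseudorandom order. Each group was measured in pooled tissue of 10 to 15 nuclei from the side of the trained eye, on 3 array designs labelled A, B and C. This gave 6 arrays, 1 for each training group and design, so neither group had a replicate on any design. Median log2 signal was 4.79 in the unpaired and 4.83 in the paired array of design A, 4.32 in both arrays of design B, and 3.03 and 3.02 in design C. The number of arrays limits the precision, and no difference between the pools has a replicate check or a p-value.

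The first comparison asked which transcripts differed in level between the nuclei of mice trained with paired and with unpaired stimuli. Gabra6, a GABA receptor subunit typical of cerebellar granule cells, was higher in the paired pool on both of its kept probe sets, which lay on design A. One had a log2 signal of 5.71 in the unpaired and 6.45 in the paired pool, a log2 ratio of 0.73, and the other 4.63 and 5.67, a log2 ratio of 1.04 or 2.06-fold. No other gene with several kept probe sets had all of them at least 1.5-fold apart in the same direction. At the other end, a probe set of Gramd3 on design C was 2.17-fold lower in the paired pool, with a log2 signal of 3.71 against 4.83, while other Gramd3 probe sets had log2 ratios of -0.15 on design B and 0.32 on design A. These were the only probe sets past 2-fold among the 18351 kept, 1 higher and 1 lower. Past 1.5-fold were 64 higher and 61 lower probe sets, and 99.3% of the kept probe sets lay within 1.5-fold. The log2 ratios of all kept probe sets had an SD of 0.19. In simulated data with a noise SD of 0.2, 0.34% of unchanged probe sets lay past 1.5-fold. Noise of that size would therefore give part of these counts without any change.

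On design A, Prkcd, a protein kinase C, was higher in the paired pool with a log2 ratio of 0.89, and its other probe sets gave 0.52 and 0.14. Slc2a3, a neuronal glucose transporter, had a log2 ratio of 0.78 on one of its 4 probe sets, and H2-Q5, a class I histocompatibility gene, had 0.74. On design B the largest log2 ratios were 0.89 for the ubiquitin ligase gene Rnf34, 0.86 for Agpat5, a lysophospholipid acyltransferase gene, 0.85 for Slc17a6, the vesicular glutamate transporter of the projection neurons, and 0.82 for Nap1l5. On design C they were 0.93 for Daam1, a regulator of actin assembly, 0.79 for Dclk1, a doublecortin-like kinase gene, 0.77 for 2900060B14Rik and 0.76 for Ttll7, a tubulin-modifying enzyme gene.

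Among the lower probe sets of design A, Actb had a log2 ratio of -0.93, Gnb1, a G protein beta subunit, -0.91, Spg21 -0.80 and Ubqln2, a ubiquitin-binding protein gene, -0.78. Design B had Sec62, a protein translocation gene, at -0.79, the transcription factor genes Mxd1 and Maf at -0.76 and -0.75, and Krtcap2 at -0.69. On design C, after Gramd3, came the transcription factor gene Camta1 at -0.80, the splicing factor gene Son at -0.74 and Rcbtb2 at -0.73. Of these 24 probe sets, 10 carried a suffix that marks less specific probes. Of the 19 genes with another kept probe set, 7 had all probe sets in one direction (Gabra6, Prkcd, Rnf34, Agpat5, Daam1, Actb and Krtcap2) and 12 had probe sets in both directions. Direction was all they shared in several cases: the smallest log2 ratio was 0.027 for Rnf34, 0.035 for Agpat5, 0.028 for Daam1 and -0.070 for Krtcap2. The probe set of highest signal rank within its design gave 0.035 for Agpat5, 0.028 for Daam1 and 0.14 for Prkcd. For Prkcd it lay on design C, with a log2 signal of 5.68 in the unpaired pool. The Prkcd probe sets on design A had higher log2 signals, 5.84 and 6.76. Slc17a6 was among the 12 with probe sets in both directions, with log2 ratios of -0.083 and -0.0025 on design C beside the 0.85 on design B.

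How far different probe sets of one gene gave the same difference was asked next, since neither pool had a replicate array. Prkcd and Gabra6 kept their direction over their probe sets, and Dclk1 and Sec62 did not, with ranges of -0.17 to 0.79 over 4 and -0.79 to 0.44 over 5 probe sets. Across 2015 genes with a pair of kept probe sets on the same design, the log2 ratios had a Pearson correlation of 0.09 (95% interval 0.05 to 0.14). It was 0.052 with no signal filter, 0.054 at or above the 75th percentile of signal and, in an alternative chosen after seeing the data, 0.013 without suffixed probe sets. Across 2196 genes with probe sets on different designs it was -0.01 (95% interval -0.05 to 0.03). These correlations are across genes, which are not independent replicates. The SD of a single probe set estimated from the pairs was 0.20 within a design and 0.21 between designs. Of the probe sets past 1.5-fold, 45 had another kept probe set of their gene on the same design. Of these, 25 pointed the same way as the mean of the others (55.6%, exact binomial 95% interval 40.0 to 70.4). On other designs 25 of 54 did (46.3%, interval 32.6 to 60.4). A gene could enter more than once, as Gabra6 did with both probe sets, and the intervals do not allow for this.

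Markers of the cell types that a dissection of the nuclei could hold were compared as lists, each by the median log2 ratio of its genes. Granule cell markers were higher in the paired pool, with 13 of 17 measured genes higher and a median of 0.10 (percentile 99.4 among matched random lists). They included Gabra6 with a mean log2 ratio of 0.89, the cadherin gene Fat2 with 0.47 and Cadps2 with 0.40, while Kcnd2 stood at -0.52. Purkinje cell markers were also higher, with 12 of 16 genes higher and a median of 0.09 (percentile 98.4). Shisa6 had a log2 ratio of 0.48, Car8, which is abundant in Purkinje cells, 0.42 and Ppp1r17 0.41, whereas Kitl had -0.59 and the Purkinje cell marker Pcp2 0.01. Both lists stood outside the central 95% of their random lists. The granule list lay inside on design B alone (5 genes, percentile 57.1) and with the brightest probe set per gene (median 0.05, percentile 90.0). The Purkinje list had 5 genes on design C alone, with a median of 0.42 (percentile 99.99), and -0.02 over 4 genes on design B, too few to place. It lay inside on design A alone (percentile 86.5) and, in an alternative chosen after seeing the data, without suffixed probe sets (percentile 95.2).

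**Figure D1:**
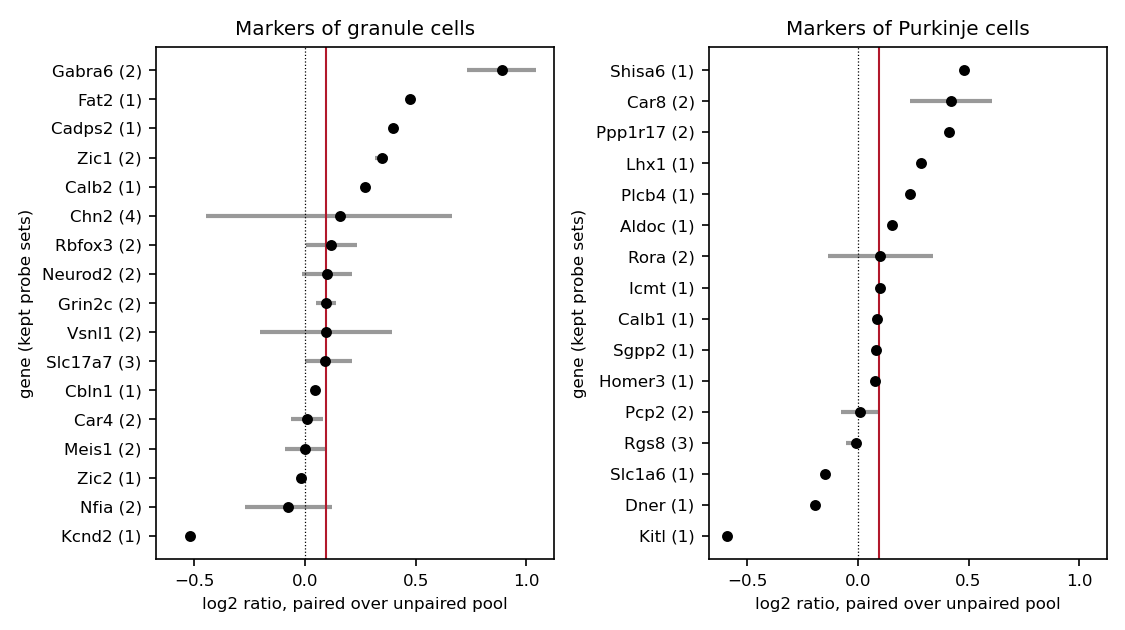
Log2 ratio of signal (paired over unpaired pool, x axis) of each measured granule cell marker (left) and Purkinje cell marker (right). Points are the mean over a gene's kept probe sets, whose number is in brackets, grey bars span the lowest to the highest probe set, and red lines are the list medians of 0.10 and 0.09. Gabra6 lies farthest to the right with 0.89, and Kitl farthest to the left with -0.59.

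Oligodendrocyte markers were lower in 20 of 25 genes, with a median of -0.08 (percentile 3.98), just inside the central 95%. Sox10, a transcription factor of the lineage, had a log2 ratio of -0.27, Gsn -0.25 and the tight junction gene Cldn11 -0.22, against 0.31 for Olig2. Markers of the deep nuclear projection neurons had a median of -0.11 over 8 genes (percentile 3.45), with Irx3 at -0.33, the neurofilament gene Nefh at -0.24 and Syt2 at -0.22, against 0.25 for Slc17a6 and 0.24 for Vamp1. With no signal filter the list had 14 genes, a median of -0.0037 and percentile 22.1, and it also lay inside at or above the 75th percentile of signal (-0.053, percentile 33.1) and without suffixed probe sets (-0.053, percentile 32.0). It stood apart under loess scaling (median -0.11, percentile 2.36), on design A alone (median -0.19, percentile 0.95) and with the brightest probe set per gene (median -0.15, percentile 2.17).

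All other marker lists lay inside the central 95% in the main analysis. Astrocyte and Bergmann glia markers had a median of -0.06 over 21 genes (percentile 14.6), with S100b at -0.33, Timp4 at -0.32, Fabp7 at -0.31 and Atp1b2 at 0.31, but stood apart in opposite directions on design B alone (0.11, percentile 98.1) and design C alone (-0.29 over 5 genes, percentile 0.44). Inhibitory interneurons of the cerebellar cortex had a median of -0.06 over 7 genes (percentile 20.8), with Sst at 0.21 and Nxph1 at 0.19, and lay above 0 with no signal filter (0.058 over 13 genes, percentile 92.08), on design A alone (0.030) and without suffixed probe sets (0.049). Oligodendrocyte precursors had 0.02 over 6 genes (percentile 55.0), a sign that turned under quantile and loess scaling, with Olig2 at 0.31 and Gpr17 at -0.23. Microglia and macrophages had 0.02 over 12 genes (percentile 68.6), with Cx3cr1 at 0.29 and C1qc at 0.16, and endothelial and mural cells -0.01 over 16 genes (percentile 46.4), with Cldn5 at -0.37 and Ctla2a at 0.34. Choroid plexus and ependyma had 0.08 over 7 genes (percentile 89.1), with Ttr at -0.45 and Calml4 at 0.19, and meninges and fibroblasts -0.03 over 11 genes (percentile 26.8), with Fmod at 0.46 and Islr at 0.19. Blood cells had -0.09 over 6 genes (percentile 16.8), with Hbb-b2 at -0.44 and Alas2 at 0.14, and brainstem and vestibular nuclei 0.08 over 6 genes (percentile 79.8), with Hoxb5 at 0.44 and Tph2 at -0.39. The sex check list had 0 genes above the signal filter and was not placed. Xist on designs A and B and the Y-linked gene Uty on design A were at the floor in both pools. Suffixed probe sets of the Y-linked genes Eif2s3y (log2 signal 4.50 unpaired, 4.44 paired) and Kdm5d (4.02 and 3.85) lay above the floor in both pools. Other Kdm5d probe sets were at the floor in the unpaired pool, so the check was weak.

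Gene groups tied to plasticity and to the function of the nuclei were compared in the same way. Genes of the cytoskeleton and of neurite growth were lower in the paired pool, with 40 of 55 measured genes lower and a median of -0.07 (percentile 0.52). Actb had a mean log2 ratio of -0.64, Cfl2, a cofilin that severs actin filaments, -0.55, and the kinesin gene Kif5b -0.39 over 3 probe sets, against 0.33 for the dendritic gene Map2. Both kept Actb probe sets lay on design A and carried a suffix, with log2 signals of 6.23 and 6.04 in the unpaired pool. The control probe sets for Actb were brighter, at a mean of 11.80 (3' end) and 10.71 (5' end) on the unpaired arrays, and went the other way. Their log2 ratios were 0.14 ± 0.07 at the 3' end and 0.29 ± 0.06 at the 5' end (SD over the 3 designs), and stayed above 0 under every scaling tried. The list's median lay far out on design A alone (-0.14 over 46 genes, percentile 0), and inside on design B (-0.03, percentile 25.5) and design C (-0.0032, percentile 50.6).

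Immediate early genes, which neurons induce on activity, lay inside the central 95% of their random lists (-0.08 to 0.08). Of 42 listed genes 23 were measured above the signal filter, and Fos, Arc and Npas4 were not among them. Of the 23 measured genes 14 were higher, with a median of 0.02 (percentile 67.6). With no signal filter 40 genes had a median of 0.0094 (percentile 69.5). A shift within the central 95% would not have stood apart. The labels give a sampling time of 10 to 30 min in both groups, and its bearing on these genes was not tested. Egr1 had a log2 ratio of 0.39, Junb 0.25 over its probe sets and Gadd45g 0.25, while Jund had -0.35. Glucocorticoid-responsive genes were higher in 14 of 21 genes, with a median of 0.07 (percentile 96.6), inside the central 95%. It lay outside under loess scaling (0.07, percentile 97.5) and on design B alone (0.22 over 5 genes, percentile 99.6), and further inside with the brightest probe set per gene (0.035, percentile 84.2). Klf9 had 0.31, Sgk1 0.25 and Nfkbia 0.23, against -0.37 for Bcl6 and -0.27 for Cebpd.

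Synaptic and channel genes lay inside their random lists, though 3 of these lists stood apart under an alternative. Glutamate receptors and their scaffolds had a median of 0.02 over 23 genes (percentile 67.2), whose sign turned under quantile and loess scaling and which stood apart with no signal filter (0.051, percentile 99.13), with Nptx1 at 0.44, Gria1 at 0.32 and Grik3 at -0.43. Genes of GABA and glycine transmission had 0.03 over 16 genes (percentile 75.5) but -0.15 at or above the 75th percentile of signal (percentile 1.0), with the GABA-synthesising enzymes apart, Gad2 at 0.44 and Gad1 at -0.41. Potassium and HCN channels had -0.0027 over 31 genes (percentile 59.1), above 0 under quantile and loess scaling, with Kcnd2 at -0.52 and Kcna6 at -0.40. Voltage-gated sodium and calcium channels had -0.05 over 17 genes (percentile 17.0), with Scn1a at -0.41 and Cacna1a at 0.38. Their median was above 0 with no signal filter (0.042, percentile 93.89) and on design A alone (0.077, percentile 84.7). The synaptic vesicle and release machinery had 0.01 over 39 genes (percentile 74.2), with Cadps at -0.46, Sv2a at -0.41, Syn1 at -0.36 and Rab3b at 0.35. Its median was 0.087 on design A alone (percentile 99.83) but -0.097 on design C alone (percentile 2.72). It was also under 0 at or above the 75th percentile of signal (-0.056, percentile 11.5) and with the brightest probe set per gene (-0.038, percentile 26.0). Kinases, phosphatases and second messenger signalling had -0.0018 over 49 genes (percentile 59.2), above 0 under the same scalings, with Prkcd at 0.52, the adenylate cyclase gene Adcy1 at 0.47 and the phosphodiesterase gene Pde4b at -0.37.

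The remaining groups also lay inside in the main analysis. Extracellular matrix and perineuronal net genes had a median of -0.02 over 21 genes (percentile 36.7), with Reln at 0.37 and Plat at -0.35. Heat shock and unfolded protein response genes had 0.03 over 33 genes (percentile 88.3), with Dnajb4 at 0.37, Hspa1a at 0.35 and Pdia3 at -0.36. Oxidative phosphorylation genes had -0.02 over 60 genes (percentile 52.0), above 0 under loess scaling, with Ndufb9 at -0.31 and Ndufs7 at 0.27, and ribosomal protein genes -0.02 over 31 genes (percentile 41.4), with Rps26 at -0.28, Rpl10a at -0.22 and Rps13 at 0.20. Genes of inflammation and reactive glia had 0.04 over 20 genes (percentile 88.6), with the interferon-induced gene Ifit3 at 0.51 and Serpina3n at -0.22. Sterol and lipid synthesis genes had -0.05 over 25 genes (percentile 14.6) but stood apart with the brightest probe set per gene (-0.10, percentile 1.57), with Fasn at -0.28 and Cyp51 at -0.24. Medians of lists inside the central 95%, immediate early genes apart, turned sign in 41 of 238 comparisons with an alternative. Of the 28 lists assessed, 3 stood apart, where 1.4 would by chance if the genes within a list varied independently. Genes of a cell type or process may vary together, and more lists would then stand apart by chance.

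**Figure D2:**
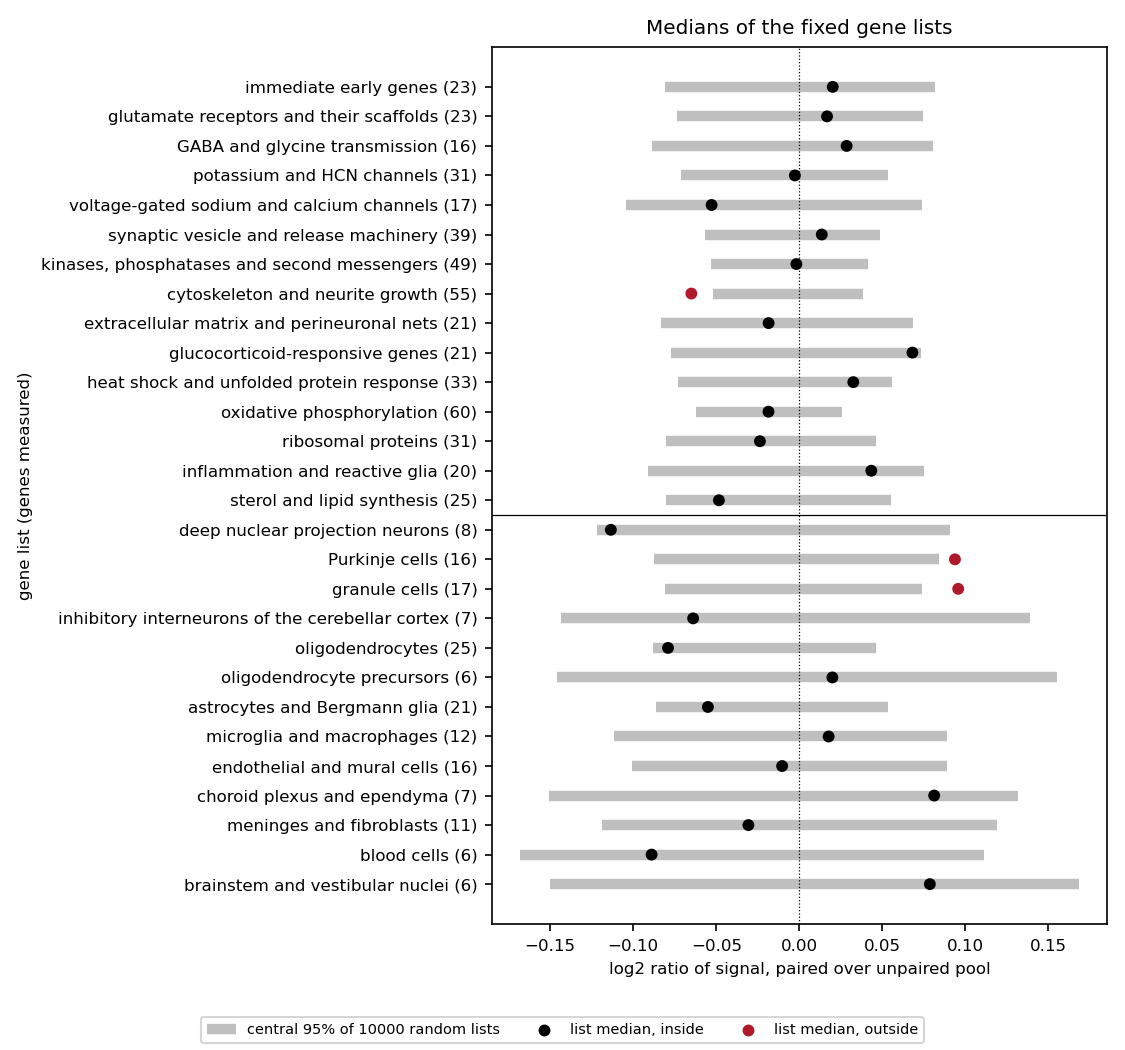
Median log2 ratio of signal (paired over unpaired pool, x axis) of the 28 assessed gene lists, process lists above the line and cell type markers under it, with the number of measured genes in brackets. Grey bars are the central 95% of 10000 matched random lists, and red points are the 3 medians outside them: cytoskeleton and neurite growth at -0.07, Purkinje cells at 0.09 and granule cells at 0.10.

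Control probe sets present on all designs asked how alike the arrays of the pools were. The 9 probe sets for the bacterial and phage transcripts that are added at hybridisation were lower on the paired arrays, with a mean log2 ratio of -1.63, or 3.09-fold, and means of -1.67, -1.54 and -1.67 on designs A, B and C. Whether the hybridisation mixtures of the groups were prepared separately is not given in the sources used here, and a lower amount added was not tested. The control probe sets for mouse messenger RNAs had mean log2 ratios of 0.15, 0.14 and 0.18 on designs A, B and C. A weaker response of the paired arrays to all transcripts alike would not part the spiked-in transcripts from them. Whether such a uniform difference was present as well cannot be decided. The median log2 ratio of the brighter probe sets was set to 0, so all these log2 ratios are relative to mouse signal. The 3 probe sets for 18S ribosomal RNA had a mean of -0.76, and the 13 for mouse messenger RNAs 0.16. The 5' minus 3' difference of the log2 ratios was 0.15 ± 0.01 for Actb and 0.34 ± 0.09 for Pcx, and 0.06 ± 0.11 for Gapdh and -0.07 ± 0.11 for Tfrc (SD over the 3 designs). The 5' probe set of Tfrc had a mean log2 signal of 2.47 unpaired and 2.48 paired, under the floors of designs A (3.28) and B (3.15). The difference for Tfrc therefore says nothing on RNA integrity. The mean log2 ratios of the control classes kept their signs under every scaling tried. Under quantile scaling the difference for Actb was 0.0032 ± 0.32, with -0.36 on design C, and that for Pcx 0.31 ± 0.08.

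**Figure D3:**
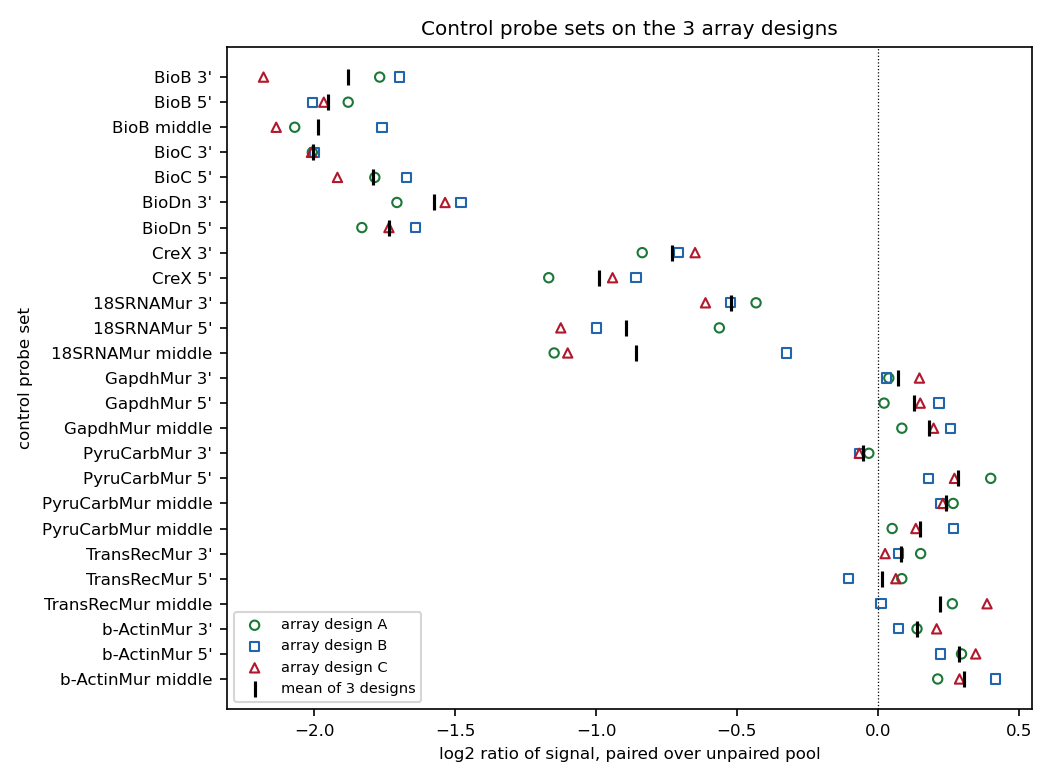
Log2 ratio of signal (paired over unpaired pool, x axis) of control probe sets for spiked-in transcripts, 18S ribosomal RNA and mouse messenger RNAs, 1 symbol per array design and a bar at the mean of the 3 designs. Spiked-in transcripts lie between -2.18 and -0.65 and mouse messenger RNAs between -0.10 and 0.42.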

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

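Leaving out probe sets with a letter suffix, leaving out Gabra6, the other scalings of the control probe sets and the second marker lists were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because the values come from no test and each group had 1 array per design.

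The 64 higher and 61 lower probe sets past 1.5-fold became 112 and 99 with no signal filter, 24 and 29 at or above the 75th percentile of signal, and 41 and 33 without suffixed probe sets, where fewer or more probe sets enter by construction. Designs A, B and C alone gave 15, 33 and 16 higher and 21, 18 and 22 lower ones. Past 2-fold, the count of higher probe sets was 0 with a floor at the median, above that percentile, on design B or C alone and without suffixed probe sets, and 64 at a 1.5-fold threshold. That of lower ones was 0 above that percentile, on design A or B alone and without suffixed probe sets, and 61 at 1.5-fold.

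Loess scaling made 5 lists stand apart in place of 3. The cytoskeleton list had a median of -0.031 on design B alone and -0.0032 on design C alone, there near the middle of its random lists (percentile 50.6). The granule list had 0.051 on design B alone and 0.050 with the brightest probe set per gene, and the Purkinje list 0.088 on design A alone and 0.082 without suffixed probe sets, all inside the central 95%. The cause was not tested. Among other lists, GABA and glycine transmission turned to -0.15 at or above the 75th percentile of signal. Astrocytes and Bergmann glia turned to 0.11 on design B alone, but had -0.29 on design C alone (percentile 0.44). With the brightest probe set in place of the mean, the gene values of Dclk1 (-0.17), Nap1l5 (-0.077), Slc17a6 (-0.0025), Ttll7 (-0.26), Sec62 (0.33) and Ubqln2 (0.10) changed sign. The correlation of probe sets on the same design was 0.013 without suffixed probe sets, over 1084 genes.

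The immediate early genes stayed inside the central 95% under every alternative that measured 5 or more of them, with a median of -0.025 at or above the 75th percentile of signal. Comparisons whose outcome the setting fixed, such as no floor or a filter on a single probe set, were left out of the counts that follow. For the immediate early genes and the 3 lists that stood apart, the median turned sign in 1 of 44 comparisons, and a list lost its standing in 6. Medians of the other lists turned sign in 41 of 238 comparisons and came to stand apart in 11. Gene values turned sign with the brightest probe set in 6 of 24 cases, and log2 ratios of single probe sets in 0 of 100. The 0 of 100 shows no stability, since these probe sets were chosen for large log2 ratios. A change of scaling or floor could hardly turn their sign. Signal over background limits the dim probe sets, and those under the median were left out.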

Other observations

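The second marker lists were written after the medians of the first lists had been seen, and loess scaling of the granule and Purkinje markers, the correlation of control probe sets and the comparison of signal ranks were chosen after those results had been seen. The other tests were set down before their results were known.

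Further oligodendrocyte genes were lower in the paired pool. Of 26 measured genes of the second oligodendrocyte list 19 were lower, with a median of -0.14 that lay at percentile 0 of its random lists. Nkx6-2 had a log2 ratio of -0.47, Carns1 -0.46, Plxnb3 -0.28 and Myrf, a transcription factor of myelination, -0.22, while Adamts4 had 0.25. The medians were -0.21, -0.09 and -0.09 on designs A, B and C (percentiles 0.06, 5.64 and 10.3), inside the central 95% on B and C. The second granule list had a median of 0.08 over 12 genes (percentile 95.02), led by Adcy1 at 0.47, and the second Purkinje list -0.01 over 17 genes (percentile 45.0), from Cacna1a at 0.38 to Rgs7bp at -0.18. Of the measured second-list genes, 6 granule, 3 Purkinje and 2 oligodendrocyte genes are also in a process list, and several are expressed by neurons outside the cortex as well.

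Granule and Purkinje cell markers were higher in the paired pool. After loess scaling they stood at percentile 99.97 together, against 99.96 in the main analysis. This cannot decide on a difference between arrays that depends on signal, since the random lists were already matched on signal rank. Percentile 99.2 for the granule list without Gabra6 decides nothing on the share of that gene, since leaving out 1 of 17 members hardly moves a median. A hypothesis is that the paired dissection held more cerebellar cortex and less white matter. The second granule and Purkinje lists as 1 list stood at percentile 98.61, and the second oligodendrocyte list at percentile 0. That combined granule and Purkinje list stood apart on no single design (percentiles 69.7, 93.81 and 22.75 on A, B and C). The second Purkinje list alone lay near the middle of its random lists (percentile 45.0). Other lists with cells of the cortex were not higher in the main analysis. Inhibitory interneurons of the cerebellar cortex had a median of -0.06 (percentile 20.8), and astrocytes and Bergmann glia -0.06 (percentile 14.6). Both medians turned sign under some alternatives, so they decide little. Without suffixed probe sets they were 0.049 (percentile 69.5) and 0.0029 (percentile 68.2). Gabra6, at 0.89, also lay well above the next granule marker, at 0.47. Training itself stays open as an untested explanation, since each group had 1 pool.

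Log2 ratios of one gene did not go together between designs. Dim probe sets are argued against as the cause, since the correlation was -0.00013 (95% interval -0.07 to 0.07) over 817 genes with both probe sets at or above the 75th percentile of signal. Error of the hybridisations alone cannot be told apart, because the log2 ratios of 13 mouse control probe sets correlated between designs by 0.307 at the lowest and 0.747 at the highest, too few to decide. Probe sets that read different transcripts of a gene may also contribute: signal ranks correlated by 0.19 between designs over all probe sets and 0.078 over kept ones (0.17 within a design), but pairs with close ranks, which correlated by -0.0063, numbered 841 where random pairing gives 793.1, so this cannot be told apart either. Pools that differed in few transcripts would give the same picture.

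The cytoskeleton and neurite growth list was lower in the paired pool. Less specific probe sets are argued against as its cause, since without suffixed probe sets its median stood at percentile 0.07 over 48 genes. On design A 32 of 46 genes were lower (median -0.14), on B 12 of 22 (-0.031) and on C 7 of 13 (-0.0032), a difference between designs that was not tested, and the control probe sets for Actb went the other way. A different mix of cells was not tested for this list and stays open, since oligodendrocyte markers were lower and granule and Purkinje markers higher, and the projection neuron list (-0.11, percentile 3.45) shares Nefh and Nefm with it. A difference in RNA integrity and training itself were not tested and stay open too. The 5' minus 3' difference was 0.15 for Actb, but 0.0032 under quantile scaling, 0.34 for Pcx and 0.06 for Gapdh. That of Tfrc (-0.07) cannot be read, since its 5' probe set lay near background.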
